A study of Danio rerio with 3 samples.

How the data were processed

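RNA was extracted from whole zebrafish (Danio rerio) embryos freed of their chorions, and the molecule sequenced was poly(A) RNA, per the labels. There were 3 libraries, 1 in each of 3 groups. The first came from wild-type embryos with no treatment given at 4.3 hours post fertilisation (hpf), the dome stage. The other two came from embryos injected into the yolk at the 1-cell stage with 1 nl of a solution holding 0.65 ng of wheat germ agglutinin (WGA), a lectin that binds glycosylated nucleoporins and blocks transport through the nuclear pore complex. Of these, the first was collected at 4.3 hpf and the other at 5 hpf, when the embryos looked like dome stage. The labels give no mock injection for the control, so the comparison with control also contains any effect of injection itself. They do not say how many embryos went into a library.

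The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the total of mapped fragments), rounded to 2 decimals, for 25386 genes identified by NCBI Gene number and symbol. The submitters' processing notes name Trimmomatic 0.36, Bowtie2 2.2.5, RSEM 1.2.8 and the genome build GRCz11, without giving their roles or settings. The annotation release is not given in the sources used here, and neither is any scaling between libraries. Each column was matched to its library by its name. RSEM, if it made these values, shares reads that match several genes among them by estimate, so values of near-identical gene copies (zinc-finger arrays, keratins, hsp70 and hnrnpa0 copies) are uncertain one by one.

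FPKM values carry no read numbers, so the absolute depth is unknown and no counting interval is given for any value. The relative depth could be read from low genes, because genes with equal small read numbers in 2 libraries have a fixed FPKM ratio. That ratio was taken as the sharpest peak among genes at FPKM of 0.1 to 1 in both libraries. Only ratios close to equal depth were searched, so a difference as large as 2-fold could not have been found. The peak ratio was 0.967 for WGA at 4.3 hpf over control (3704 genes), 0.964 for WGA at 5 hpf over control (3894 genes) and 0.999 between the WGA libraries (4215 genes). The peaks stood at 1.54, 1.26 and 1.67 times their local mean, in that order. Within the range searched, the WGA libraries were 3.4% and 3.8% deeper than the control, if mapped reads alone set the value of 1 read. The library sums were 430459.3 FPKM in the control, 401114.5 in WGA at 4.3 hpf and 411177.9 in WGA at 5 hpf.

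With 1 library per group there is no replicate error, and no p-value across genes was computed. Each comparison is the log2 ratio of (FPKM + 1) in 2 libraries, with a pseudocount of 1, which understates the change of low genes. Folds in the text are on this scale. Genes were counted as higher or lower at 2-fold or more, among genes at FPKM of at least 1 in either library. Fixed gene lists (23 lists, 684 entries) were written before the data were examined. Of the entries, 666 matched a gene, 24 of them through a current symbol or synonym in the NCBI gene table of assembly GRCz12tu, which was used for names alone and holds 23416 of the 25386 gene numbers. The 18 unmatched entries include 1 clone name in the p53 list that matched an unrelated gene by synonym. It was left out after the values of that list had been seen, and the values with it kept are given among the alternatives. Of the genes measured, 44 of 511 belong to more than 1 list. The list medians were computed over members at FPKM of at least 1 in any library and set beside 10000 random lists of the same size, drawn from 14349 genes in 20 bins of mean log2(FPKM + 1). The share of random lists describes these libraries and is not a test of the conditions. Of the lists, 21 gave a value. Mitochondrially encoded genes had 0 matches in the table, and the later gastrula and segmentation list had 2 measured genes.

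The genes named in the text were chosen by a rule fixed before the data were examined. For each comparison these are the 8 highest and 8 lowest genes with a gene symbol other than a clone name, at FPKM of at least 5 in either library. They also include up to 4 members per list with the largest absolute ratio, and klf17, vox, tbxta (listed as ta), gsc, krt4, nanog, pou5f3, sox19b and buc. Members outside this rule in the comparison concerned that complete a count of 5 or fewer, namely aplnrb, lef1, otx1b, btg4, slbp2, lsm14b, rps8b, dnajb1a, herpud1, creld2, baxb, elavl3, snrpd2, cldne, ndr2 and fgf8a, were named after their values were seen, although the rule names btg4, slbp2, lsm14b, snrpd2 and fgf8a in another comparison. So were genes of the families in the closing section. Not every gene that the rule names is reported here.

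Both comparisons with the control share its 1 library. As a description of that sharing under small noise, 100 sets of 3 unchanged libraries were simulated. The noise was normal, with a robust SD from the spread between the WGA libraries (0.122 to 0.195 log2 per library, by expression bin). It leaves out the larger differences of that pair, so few calls at 2-fold were possible. That spread also contains any difference between 4.3 and 5 hpf, and no spread between control libraries could be measured. The calculations were tested on simulated data for WGA at 4.3 hpf against control. Changes were planted only in genes at a mean FPKM of at least 5, although genes are counted from FPKM 1. Of 100 genes planted at 3-fold 97.0% were called and of 100 planted at 8-fold 100.0% were called, against 0.01% of 13553 unchanged genes. That last share comes from the same small noise, whereas 1.13% of genes differed by 2-fold or more between the WGA libraries. It is therefore not an error rate of the real counts. A list of 25 lowered genes lay at percentile 0.0, and 5 of 100 lists of unchanged genes fell outside the random 95% band.

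The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at FPKM 5, rescaling to TPM, median-of-ratios scaling, scaling to the ribosomal protein genes, a 4-fold threshold, and list means. The list values under TPM and ribosomal protein scaling, the list values with the clone-name entry kept and the values of single genes under other pseudocounts and scalings were added after seeing the data. Planned checks of gene length and of the miR-430 site in 3' UTRs were not run, since they need a genome and annotation of the authors' build, which were not used here. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.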

Results

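Poly(A) RNA was profiled in 3 libraries of whole zebrafish embryos to ask how blocking nuclear pores with WGA affects zygotic genome activation, the onset of transcription from the embryo's own genome. One library came from control embryos at 4.3 hpf (dome stage). The second came from WGA-injected embryos of the same age and the third from WGA-injected embryos at 5 hpf, when they looked like dome stage. The control thus serves as a time-matched reference for the second library and as a stage-matched reference for the third. Genes at FPKM of at least 1 numbered 13739 in the control, 13128 in WGA at 4.3 hpf and 13128 in WGA at 5 hpf. Genes listed above 0 numbered 22790, 21815 and 21892. There was 1 library per group, so no difference below has a replicate check. The nearest measure of spread is the pair of WGA libraries, where 152 of 13478 genes (1.13%) differed by 2-fold or more and log2(FPKM + 1) correlated across genes at r = 0.986. Across genes the control correlated at r = 0.916 with WGA at 4.3 hpf and at r = 0.932 with WGA at 5 hpf. Genes are not independent replicates.

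At the matched time of 4.3 hpf, genes of the first zygotic wave were much lower in WGA embryos, and a smaller set of maternal transcripts was several-fold higher. All 34 measured first-wave genes lay below control and 33 of them by 2-fold or more. Their median log2 ratio was -2.18 (4.53-fold lower, SD over members 0.55), and 0 of 10000 expression-matched random lists had a median as low. The first-wave gene nnr (NCBI Gene 321023) stood at 266.84 FPKM in control and 27.24 FPKM in WGA embryos, 9.48-fold lower. The RNA polymerase III subunit gene polr3gla (447901) was at 153.46 and 16.42 FPKM, 8.87-fold lower. The homeobox repressor vox (64807), which acts in the ventral embryo, was at 84.67 and 17.89 FPKM. The Krüppel-like factor gene klf17 (65238) was at 109.5 and 32.77 FPKM, 3.27-fold lower. The secreted peptide gene apela was 6.91-fold lower and asb11 was 7.44-fold lower. The member that did not reach 2-fold was the apelin receptor gene aplnrb, named after its values were seen, at a log2 ratio of -0.56.

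Genes of the 2 extra-embryonic lineages of the blastula stood among the lowest. The yolk syncytial layer list had a median log2 ratio of -2.34 (5.06-fold lower, SD over members 1.2), with 10 of 12 measured members lower by 2-fold or more and 0 higher. Its endodermal and yolk regulators gata6 and hnf4a were 9.65-fold and 9.22-fold lower, at 20.14 against 1.19 FPKM and 15.23 against 0.76 FPKM. The apolipoprotein gene apoeb was at 457.2 FPKM in control and 55.99 FPKM in WGA embryos. The enveloping layer, the outer epithelium of the blastula, had a list median of -1.90 (3.73-fold lower, SD over members 1.13), with 18 of 24 members lower by 2-fold or more and 0 higher. Its keratin genes krt5, krt92 and krt4 were 10.2-fold, 9.41-fold and 8.10-fold lower. For both lists 0 of 10000 random lists had a median as low. The lowest gene of all by the naming rule was ctsll, a cathepsin L-like protease gene, at 21.9 FPKM in control and 1.17 FPKM in WGA embryos, 10.6-fold lower. The adenylate kinase gene ak3 was 9.62-fold lower.

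Germ layer and axis genes were also low. Of 25 mesendoderm and Nodal target genes, 17 were lower by 2-fold or more and 0 were higher, with a median log2 ratio of -1.80 (SD over members 1.01). The T-box genes ta (30399), the zebrafish brachyury gene now called tbxta, and tbx16 were 5.25-fold and 6.65-fold lower. The organizer gene gsc (30212) was at 19.65 FPKM in control and 3.87 FPKM in WGA embryos, and the forkhead gene foxa3 was 6.64-fold lower. Of 21 dorsal organizer genes 17 were lower by 2-fold or more and 0 were higher (median -1.61, SD 0.94). Of 18 BMP and ventral genes 13 were lower and 0 higher (median -1.90, SD 1.11), with the ventral repressor gene ved 6.52-fold and the ligand gene bmp7a 6.27-fold lower. Of 17 neuroectoderm genes 11 were lower and 1 higher (median -1.73, SD 1.2), with zic2b 5.96-fold and sox19a 5.48-fold lower. Of 16 Wnt and FGF genes 9 were lower and 2 higher (median -1.23, SD 1.38). In that list sp5a and fgf8a were 5.37-fold and 4.55-fold lower, while the ETS factor gene etv5a was 4.48-fold higher and lef1, which encodes a Wnt effector, had a log2 ratio of 1.07. The neuroectoderm member that was higher was the homeobox gene otx1b, at a log2 ratio of 1.36. At most 1 of 10000 random lists was as low as any of these 5 lists, which share members.

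Among maternal transcripts the picture was mixed. The oocyte and maternal list had a median log2 ratio of 0.25 (SD over members 0.90), and 11 of 10000 random lists were as high. In it 5 of 41 members were higher by 2-fold or more, 2 were lower and the other 34 lay within 2-fold. The Balbiani body gene buc (334375) was at 70.66 FPKM in control and 349.7 FPKM in WGA embryos, 4.89-fold higher, and the polyadenylation factor gene cpeb1b was 5.11-fold higher. The other members higher by 2-fold or more were btg4, slbp2 and lsm14b, at log2 ratios of 1.16, 1.21 and 1.35. The members lower by 2-fold or more were the Nodal co-receptor gene tdgf1 (2.91-fold) and stm, the starmaker gene of the otolith matrix (8.71-fold). In the germ plasm list 4 of 19 members were higher and 0 lower (median 0.38, SD 0.90), and 278 of 10000 random lists were as high. That median lay just inside the random band (percentile 97.23). Its Tudor-domain genes tdrd6, tdrd1 and tdrd7a were 9.45-fold, 2.69-fold and 2.12-fold higher. The maternal regulators of genome activation had a median of -0.02, within the random band, with 3 of 14 higher and 0 lower. Its SoxB1 factor gene sox19b (64812) was at 56.6 FPKM in control and 292.6 FPKM in WGA embryos, and eomesa and ep300a were 2.40-fold and 2.38-fold higher. The pluripotency factor genes nanog (792333) and pou5f3 (30333) were at 1094.35 and 717.3 FPKM in control and 934.97 and 423.56 FPKM in WGA embryos. The sign of this list's median was positive under TPM and ribosomal protein scaling. The highest genes by the naming rule were sh2d5 (10.5-fold) and tdrd6, followed by dnajc5ga, ssh2a, fam129bb, mtus1a, luzp1 and zbtb21 at 7.37-fold to 6.60-fold.

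Genes of the nuclear pore itself differed little. None of 32 nucleoporin genes differed by 2-fold (median -0.09, SD 0.29). The largest ratios were 1.77-fold higher for ahctf1, which encodes the pore-seeding protein ELYS, and 1.73-fold lower for nupl2. Nuclear transport receptor genes had 2 of 36 higher and 3 lower (median -0.09, SD 0.58), including the importin gene kpna5, 2.59-fold lower. The signs of both medians were positive under TPM and ribosomal protein scaling. Ribosomal protein genes were lower in 77 of 78 cases, 15 of them by 2-fold or more, while rps8b was higher at a log2 ratio of 1.32 (median -0.72, 1.65-fold lower, SD 0.34). The spliceosome list had 37 of 38 members below control and 5 by 2-fold or more (median -0.56, SD 0.48), among them hnrnpa0a (4.81-fold), hnrnpa0b (3.79-fold) and snrpd2 (log2 ratio -1.02). The ribosome biogenesis list had a median of -0.33 with 1 of 32 lower by 2-fold, the nucleolar GTPase gene gnl3. For these 3 lists at most 2 of 10000 random lists were as low. Under scaling to the ribosomal protein genes their own median is 0 by construction, and the spliceosome and ribosome biogenesis medians turned positive (0.15 and 0.37).

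The heat shock and p53 lists had medians below the random band, with members on both sides of control. In the heat shock and unfolded protein list 7 of 26 were lower by 2-fold or more and 3 higher (median -0.31, SD 1.31), and 130 of 10000 random lists were as low. The small heat shock gene hspb1 was at 714.45 FPKM in control and 85.41 FPKM in WGA embryos, and hsp90aa1.2 was 6.92-fold lower. The members that were higher were dnajb1a, herpud1 and creld2, at log2 ratios of 1.83, 1.55 and 1.32. In the p53 and DNA damage list 4 of 22 were lower and 2 higher (median -0.31, SD 1.05, 18 of 10000 random lists as low), with gadd45ba 5.25-fold lower, the p53 inhibitor gene mdm4 6.17-fold higher and baxb at a log2 ratio of 1.09. Both medians turned positive under ribosomal protein scaling (0.41 and 0.37). The cell cycle list had 7 of 36 lower and 0 higher (median -0.21, SD 0.95, 0.52 under ribosomal protein scaling), and 250 of 10000 random lists were as low. In it the cyclin gene ccnd1 was 5.73-fold and the CDK inhibitor gene cdkn1ca 6.22-fold lower. Interferon and innate immune genes had 2 of 9 lower and 1 higher (median -0.50, SD 1.22), with stat1a 4.60-fold higher. Genes of differentiated cell types had 4 measured members, of which 1, the neuronal gene elavl3, was lower by 2-fold or more (log2 ratio -1.21, list median -0.24, positive under ribosomal protein scaling).

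Over all 14263 genes measured in this pair, 1280 were lower by 2-fold or more and 1028 were higher, so that lower genes made up 55.5% of those counted. At 4-fold the numbers were 336 lower and 91 higher. The split depended on the filter and on scaling. A filter at FPKM 5 gave 783 lower and 937 higher, and TPM gave 1544 lower and 1589 higher (49.3% lower). Scaling to the ribosomal protein genes moved the median of all genes from 0.03 to 0.68 log2 and left lower genes at 16.4% of those counted (819 lower, 4170 higher). The counting rule sets no error rate across embryos.

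**Figure D1:**
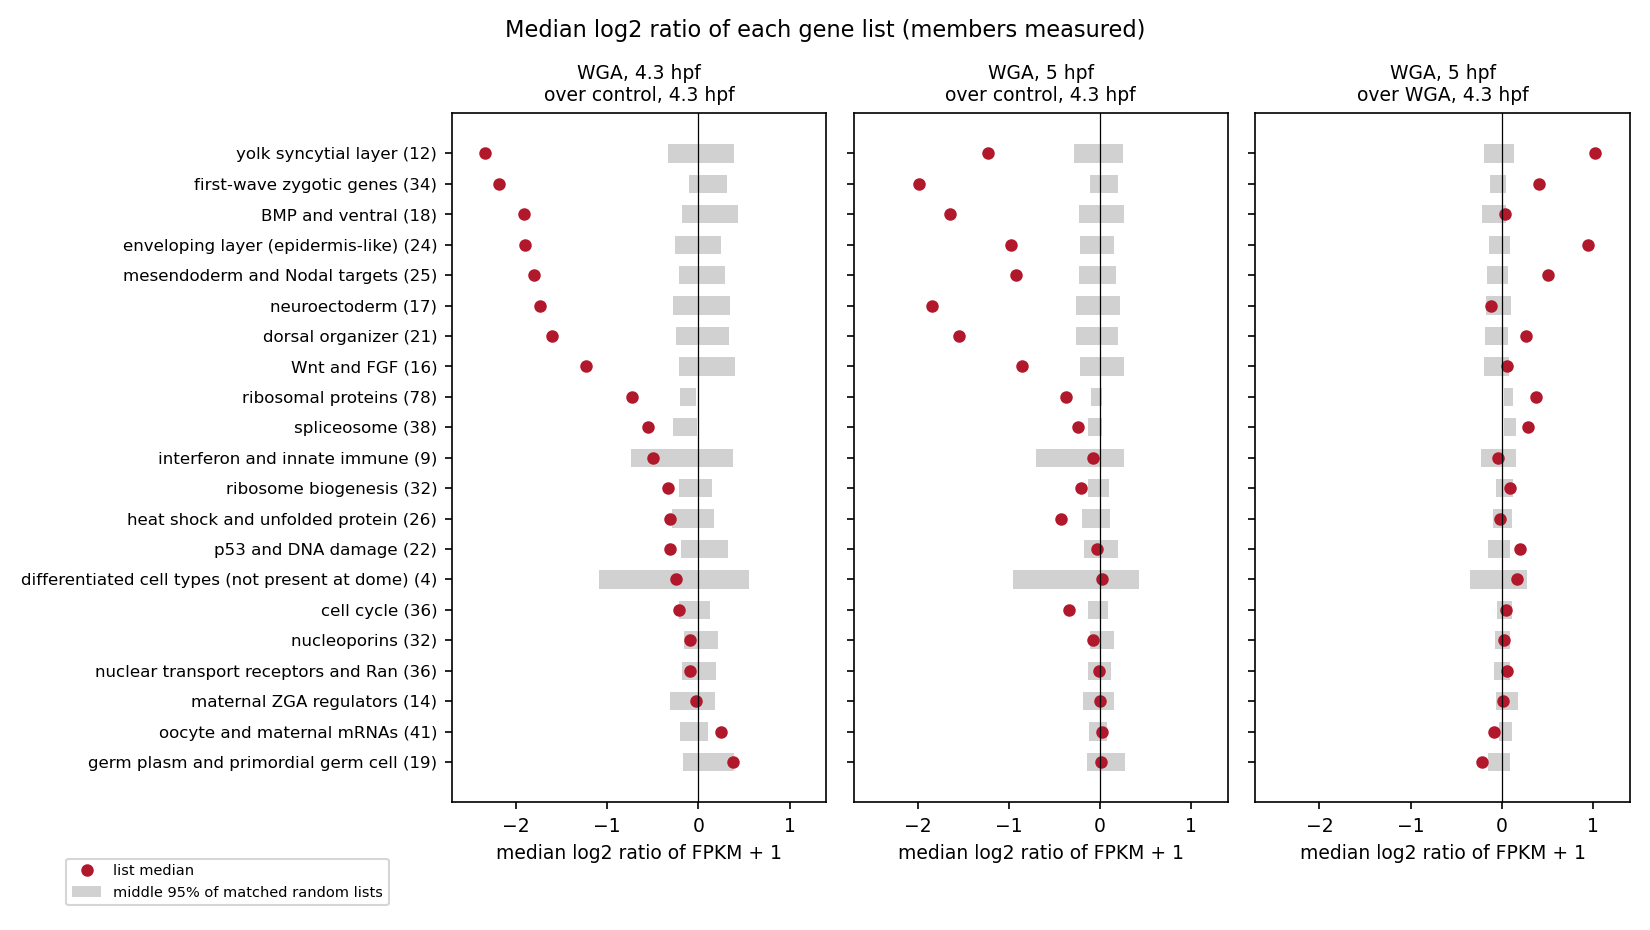
Median log2 ratio of FPKM + 1 (x axis) for each gene list (rows, with the number of measured members) in the 3 comparisons, with grey bars for the middle 95% of matched random lists. The yolk, first-wave and germ layer lists lie left of the bars in both comparisons with control, and the yolk and enveloping layer lists lie right of them between the WGA libraries; under scaling to the ribosomal protein genes the spliceosome, ribosome biogenesis and cell cycle medians change sign in both comparisons with control, and the heat shock median in that at 4.3 hpf.

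At the matched stage (WGA at 5 hpf against control at 4.3 hpf), the first-wave and axis genes were still low, and buc, tdrd6, sox19b and cpeb1b were still high. Of 34 first-wave genes 29 were lower by 2-fold or more and 0 higher, with a median log2 ratio of -1.99 (3.96-fold lower, SD over members 0.67). The lowest gene was the Hairy-related repressor gene her5 (30285), at 72.82 FPKM in control and 4.59 FPKM in WGA embryos, 13.2-fold lower. The zinc-finger gene blf was 9.41-fold and the vestigial-like gene vgll4l 7.71-fold lower. The numbered zinc-finger genes znf995, znf1043, znf1137 and znf1085 were 9.73-fold to 7.35-fold lower, although reads of such genes can be shared with near copies. The GTPase gene rnd1b was 7.30-fold lower. Neuroectoderm genes had 11 of 17 lower and 1 higher (median -1.85, SD 1.24), BMP and ventral genes 13 of 18 lower and 0 higher (median -1.65, SD 0.99), and dorsal organizer genes 14 of 21 lower and 0 higher (median -1.55, SD 0.86). Named members were sox11a (5.68-fold lower), klf2a (5.75-fold lower), bmp2b (4.32-fold lower), the chemokine receptor gene cxcr4a (6.83-fold lower) and gsc (3.29-fold lower). Wnt and FGF genes had 7 of 16 lower and 1 higher (median -0.86, SD 1.14).

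Lineage genes of the yolk and outer layers lay closer to control than at 4.3 hpf but below it. The yolk syncytial layer list had 7 of 12 lower by 2-fold or more and 0 higher (median -1.23, 2.34-fold lower, SD 0.85), with mxtx1, a homeobox gene of that layer, 3.87-fold and apoeb 3.43-fold lower. The enveloping layer list had 12 of 24 lower and 0 higher (median -0.98, 1.97-fold lower, SD 0.77). Its epithelial regulator genes grhl3 and klf17 were 4.78-fold and 4.49-fold lower, and krt4 was 2.56-fold lower. Mesendoderm and Nodal target genes had 10 of 25 lower and 0 higher (median -0.92, 1.89-fold lower, SD 0.79), with tbx16 3.99-fold and ta 1.98-fold lower. For these 8 zygotic and lineage lists 0 of 10000 random lists had a median as low.

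On the maternal side tdrd6 was 9.75-fold, cpeb1b 5.56-fold, buc 5.11-fold and sox19b 5.08-fold higher than control. In contrast btg4 was at 47.92 FPKM in control and 48.91 FPKM in WGA embryos at 5 hpf, slbp2 at 40.43 and 51.64 FPKM, and tdrd7a had a log2 ratio of 0.86. The other genes at the top were sh2d5, dnajc5ga, lsm1, gpr137c, mdm4, zbtb21 and ccdc69, at 9.02-fold to 6.73-fold. The list medians themselves lay near 0: the oocyte and maternal list at 0.02 (3 of 41 higher, 2 lower, sign not kept under median-of-ratios scaling) and the germ plasm list at 0.02 (3 of 19 higher, 0 lower, sign likewise not kept). The maternal regulators had 2 of 14 higher and a median of -0.004. Nucleoporin genes again included none at 2-fold (median -0.08, SD 0.28), and transport receptor genes had 1 of 36 higher and 4 lower, among them the importin gene kpna2 (3.01-fold lower). Ribosomal protein genes had 1 of 78 lower by 2-fold (median -0.37, SD 0.24). The spliceosome list (median -0.25, 4 of 38 lower), the ribosome biogenesis list (-0.21, 1 of 32 lower) and the cell cycle list (-0.34, 9 of 36 lower) each lay below the random band. Their medians turned positive under ribosomal protein scaling. The heat shock list had 8 of 26 lower and 3 higher (median -0.43, SD 1.18, 0 of 10000 random lists as low), with hsp90aa1.2 7.15-fold and hsp70.3 7.13-fold lower. The p53 list (median -0.03) had 2 of 22 lower and 1 higher, and the interferon list (-0.08) had 2 of 9 lower and 1 higher. Differentiated cell type genes had 1 of 4 lower (elavl3, log2 ratio -1.40). The medians of the maternal regulator, nucleoporin, transport receptor, p53 and interferon lists changed sign under ribosomal protein scaling.

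Over 14158 genes, 1122 were lower by 2-fold or more and 751 were higher, so that 59.9% of those counted were lower. Under ribosomal protein scaling, which moved the median of all genes from -0.02 to 0.31, that share was 34.1% (825 lower, 1591 higher).

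Of the 1280 genes lower at the matched time, 975 (76.2%) were also lower by 2-fold or more at the matched stage and 305 (23.8%) were within 2-fold of control. Of the 1028 higher genes, 711 (69.2%) were still higher and 317 (30.8%) were within 2-fold. Both ratios use the same control library. In simulated unchanged libraries that shared a control, an average of 0.4 genes were called lower and 0.39 higher, with 0.03 called lower in both comparisons and 0 called higher in both. That noise lacked the larger differences of the real WGA pair, where 152 of 13478 genes reached 2-fold. The simulation therefore cannot tell how much of the overlap a shared control library gives. Independent lists of the observed sizes would share 100.1 lower and 53.8 higher genes. The control could not be split, so part of the overlap may come from that 1 library.

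**Figure D2:**
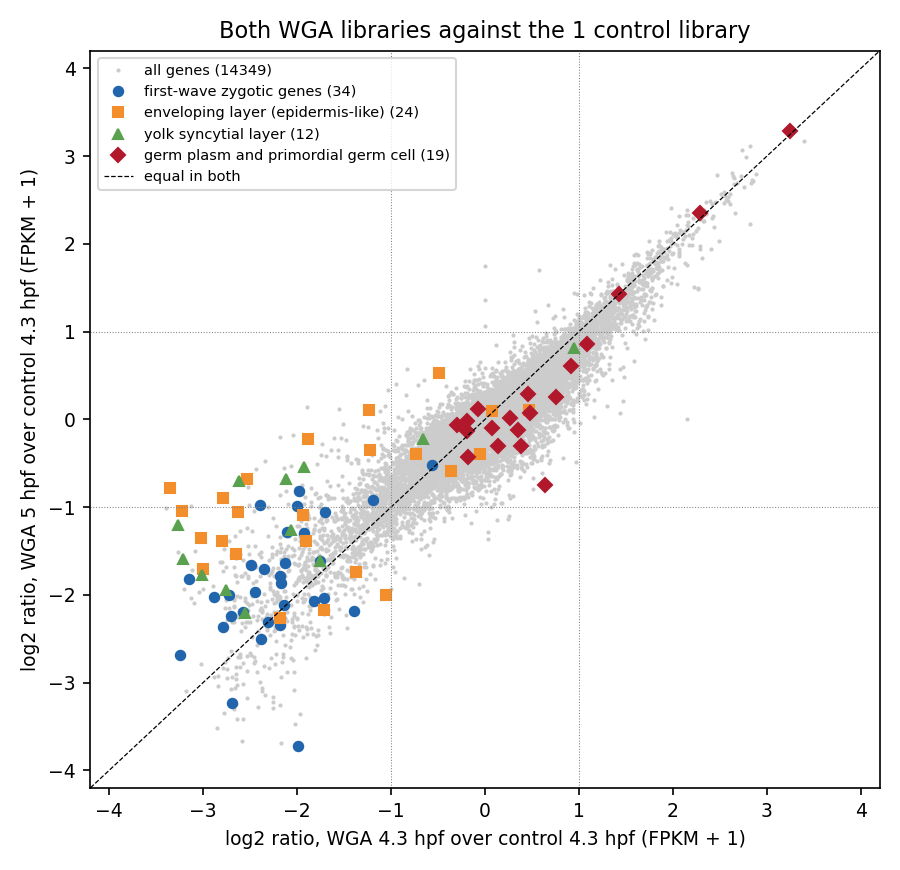
Log2 ratio of FPKM + 1 against the control library for WGA at 4.3 hpf (x axis) and WGA at 5 hpf (y axis), 1 point per gene, with 4 gene lists in colour and dotted lines at 2-fold. First-wave genes lie at the lower left (medians -2.18 and -1.99), and most enveloping and yolk layer genes lie above the dashed line of equal ratios; both axes share 1 control library, so part of the alignment may come from it.

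Between the WGA libraries (5 against 4.3 hpf), the yolk and enveloping layer genes were higher at the later time, while neuroectoderm and ventral genes were close to level. Of 12 yolk syncytial layer genes 6 were higher by 2-fold or more and 0 lower (median log2 ratio 1.02, 2.03-fold, SD over members 0.72). The members gata6, the antifreeze-like gene afp4 and apoeb were 4.21-fold, 3.80-fold and 2.35-fold higher. Of 24 enveloping layer genes 12 were higher and 0 lower (median 0.94, 1.92-fold, SD 0.97), with krt5, krt92, krt8 and the annexin gene anxa1a 5.94-fold, 4.55-fold, 3.69-fold and 3.59-fold higher. Mesendoderm genes had 6 of 25 higher and 0 lower (median 0.50, SD 0.67), with ta 2.65-fold, foxa3 2.54-fold and the Nodal target gene mixl1 2.22-fold higher. First-wave genes had 5 of 34 higher and 1 lower (median 0.41, SD 0.65). In these 4 lists 0 of 10000 random lists had a median as high. The first-wave members that were higher were ta, polr3gla (2.51-fold), mixl1, cldne and ndr2 (log2 ratios of 1.12 and 1.02 for the last 2), and the one that was lower was her5, at 17.52 and 4.59 FPKM.

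The remaining zygotic lists had smaller medians. Dorsal organizer genes had a median of 0.27 (SD 0.52), which became -0.03 under ribosomal protein scaling, with 2 of 21 higher by 2-fold or more (foxa3 and fgf8a, the latter at a log2 ratio of 1.32) and the BMP antagonist gene chd at 3.72 and 7.79 FPKM. BMP and ventral genes (median 0.03), Wnt and FGF genes (0.05) and neuroectoderm genes (-0.12) lay within the random band, with 1 of 18 higher, 1 of 16 higher and 1 of 17 lower. The positive medians among them turned negative under ribosomal protein scaling. Ribosomal protein genes were higher in 77 of 78 cases, none by 2-fold (median 0.37, SD 0.19), with rpl38 at 34.49 and 61.48 FPKM. Spliceosome genes had a median of 0.29 (SD 0.22, none at 2-fold), which turned to -0.06 under ribosomal protein scaling. The p53 list had 2 of 22 higher and 0 lower (median 0.20, -0.15 under ribosomal protein scaling), namely sesn3 (2.44-fold) and phlda3 (2.33-fold).

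Maternal and germ plasm lists had slightly negative medians at 5 hpf against 4.3 hpf, where the median of all genes was -0.05. Under median-of-ratios scaling the oocyte and maternal list stood at -0.032 and the germ plasm list at -0.165. The oocyte and maternal list had a median of -0.09 (SD 0.47) with 2 of 41 lower by 2-fold and 1 higher, and 16 of 10000 random lists were as low. The deadenylation factor gene btg4 was 2.19-fold lower and zar1l, a gene of oocytes, 2.02-fold lower. The germ plasm list had a median of -0.22 (SD 0.38) with 1 of 19 lower by 2-fold, the gene ca15b (2.60-fold), and 14 of 10000 random lists were as low. The log2 ratio between the WGA libraries was 0.06 for buc, 0.05 for nanog and -0.02 for pou5f3, and sox19b stood at 292.6 and 291.64 FPKM. Other genes at the bottom were fhdc2, phex, acd, mt2, cdca9 and ldlrap1a, 2.57-fold to 2.27-fold lower. The maternal regulators (0.02), nucleoporins (0.02), transport receptors (0.05), cell cycle (0.04), ribosome biogenesis (0.09), heat shock (-0.03), interferon (-0.05) and differentiated cell type (0.16) lists lay within the random band. The sign of each of these small medians depended on the scaling.

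In all, 104 of 13478 genes were higher by 2-fold or more at 5 hpf and 48 were lower, so that 31.6% of those counted were lower. That share was 44.2% after rescaling to TPM (117 lower, 148 higher) and 83.3% under ribosomal protein scaling (379 lower, 76 higher), where the median of all genes moved from -0.05 to -0.38.

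**Figure D3:**
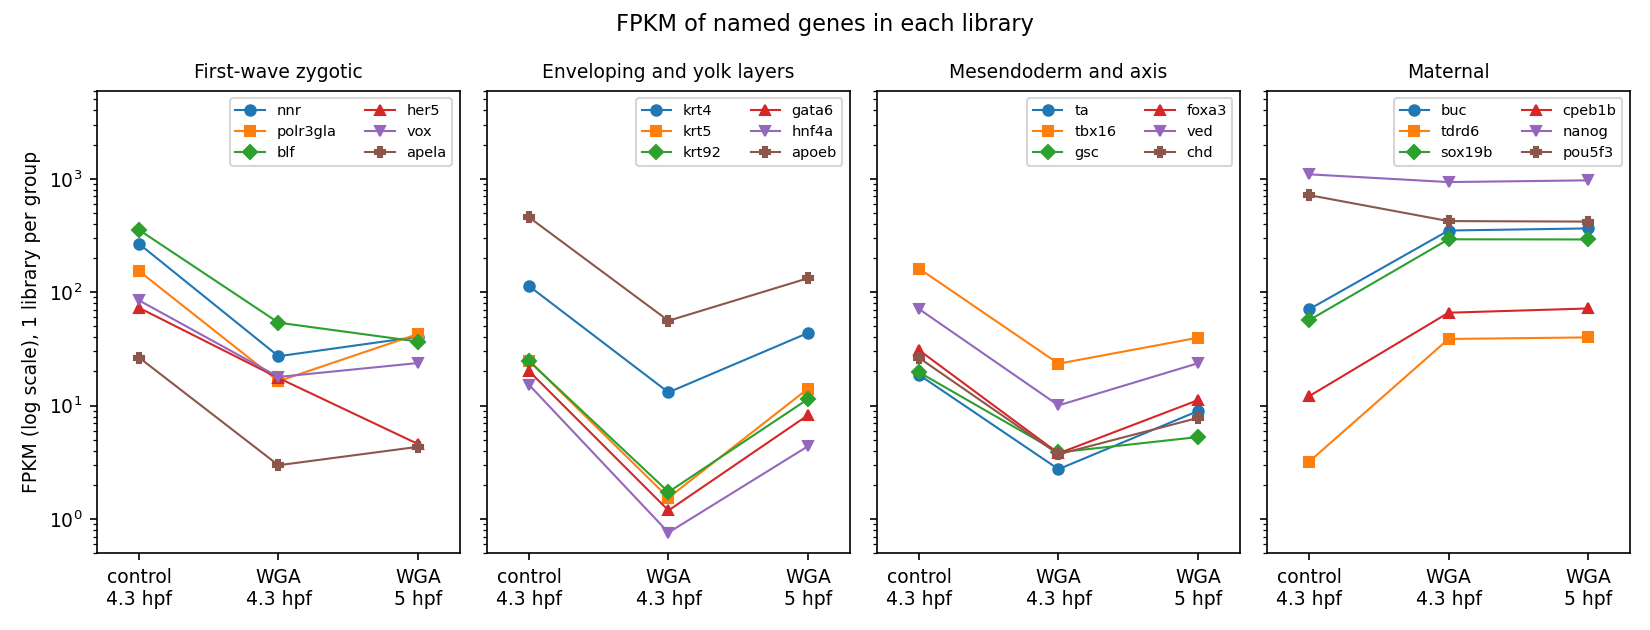
FPKM on a log axis for 24 genes in the 3 libraries (x axis), 1 point per library, with no error bars because each group has 1 library. The keratin, yolk and mesendoderm genes shown are lowest in WGA embryos at 4.3 hpf and higher at 5 hpf, her5 and blf are lowest at 5 hpf, and buc, tdrd6, sox19b and cpeb1b are higher in both WGA libraries than in control.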

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

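The rule for this part looked for opposite directions at the WGA times, and no test was planned or run for it. Of the 169 genes named by the rule, 18 stood on opposite sides of control in WGA embryos at 4.3 hpf and at 5 hpf. With 1 library per group the difference between the times was not tested. Many of these genes were named because their ratio between the WGA libraries was extreme, which favours such sign changes. In 6 of the 18 both log2 ratios exceeded 0.275, the highest SD of a ratio estimated from the spread between the WGA libraries, a dividing value chosen after the genes had been seen. The germ plasm gene ca15b had log2 ratios of 0.64 at 4.3 hpf and -0.75 at 5 hpf (32.07 FPKM in control, 50.36 and 18.72 in the WGA libraries). The germ cell gene dnd1 had ratios of 0.38 and -0.30, the telomere gene acd 0.51 and -0.79, and cdca9 0.61 and -0.61. The adaptor gene ldlrap1a had ratios of 0.68 and -0.50 and the chaperone gene dnajc3a 0.70 and -0.47. In the other 12 at least 1 of the ratios was smaller than 0.275. Above control first and below it later were phex (0.26 and -1.10), the metallothionein gene mt2 (0.13 and -1.15), the oocyte gene zar1l (0.11 and -0.91), the checkpoint kinase gene chek1 (0.18 and -0.55) and the nucleoporin gene nup153 (0.04 and -0.57). So were the germ cell gene nanos3 (0.35 and -0.12), the stress factor gene atf3 (0.38 and -0.19), birc5b (0.58 and -0.10), the RNA polymerase I gene polr1a (0.32 and -0.17) and ppan (0.38 and -0.04). The other way round were phlda3 (-1.12 and 0.10) and the DNA damage gene gadd45aa (-0.62 and 0.22). The list of differentiated cell types, with 4 measured genes, had medians of -0.243 and 0.021.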

How the results depend on the processing

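The TPM and ribosomal protein scalings of the gene lists, the kept clone-name entry and the alternatives for single genes were chosen after the results were seen; the other alternatives were planned. No paired analysis was possible because each group has 1 library. The checks of gene length and of the miR-430 site were not run, and unknown absolute depth allows no counting interval. Under median-of-ratios scaling each 2-fold count stayed within 1.5 times its value. Removing the filter cannot alter these counts, because a pseudocount of 1 keeps genes below FPKM 1 in both libraries under 2-fold. A pseudocount of 0.1 gave 1696 genes lower in WGA at 5 hpf than in control, and 207 higher and 158 lower between the WGA libraries. A pseudocount of 5 gave 475 higher and 532 lower for WGA at 4.3 hpf against control, 370 and 442 at 5 hpf, and 18 and 6 between the WGA libraries. A 4-fold threshold, stricter by construction, gave 91 and 336, 81 and 231, and 6 and 1 in that order. A filter at FPKM 5, which leaves fewer genes, gave 783 lower and 937 higher at 4.3 hpf. It gave 723 lower at 5 hpf and 49 higher between the WGA libraries. TPM, which changes both the weight of the pseudocount and the scaling between libraries, gave 1589 higher and 1544 lower at 4.3 hpf. It gave 117 lower between the WGA libraries. Ribosomal protein scaling, which shifts all genes, gave 4170 higher and 819 lower at 4.3 hpf, 1591 higher at 5 hpf and 379 lower between the WGA libraries. Lists above the random band at 4.3 hpf numbered 2 with a pseudocount of 0.1, 2 with a filter at FPKM 5 and 3 with list means, against 1, and the cause was not tested. With a 4-fold first difference, 6.5% of lower and 1.1% of higher genes were within 2-fold of control at 5 hpf, a result of starting further away. Under ribosomal protein scaling 11 list medians outside the random band changed sign, as this scaling lifts or lowers nearly all genes. Against random lists under the same scaling all kept their side of the band except heat shock at 4.3 hpf, just inside it at percentile 2.58. Against control at 4.3 hpf these were heat shock (0.414), p53 (0.366), ribosome biogenesis (0.370) and spliceosome (0.153). At 5 hpf they were cell cycle (0.031), ribosome biogenesis (0.164), spliceosome (0.127) and the ribosomal proteins (0.000, by construction). Between the WGA libraries they were dorsal organizer (-0.029), p53 (-0.145) and spliceosome (-0.061). With the clone-name entry kept, the p53 medians were -0.228, -0.018 and 0.193, the first at percentile 1.13. None of the genes named at 2-fold or more reversed under the 5 alternatives of pseudocount and scaling, but of 269 values of single genes 245 moved by more than 0.275 log2 under ribosomal protein scaling, 119 with a pseudocount of 5, 44 with 0.1 and 14 in TPM.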

Other observations

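The gene families and the tests in this part were chosen after the results were seen, apart from the median-of-ratios scaling of the gene lists, which was planned. Genes of the proteasome and of the nuclear-encoded respiratory chain were slightly lower in WGA embryos. The families were picked by gene symbol, so the respiratory chain set also holds assembly factor genes (the ndufaf genes). At 4.3 hpf, 37 of 40 proteasome subunit genes lay below control (median log2 ratio -0.42, 3 by 2-fold or more and 1 higher), as did 50 of 65 respiratory chain genes (median -0.33, 7 by 2-fold or more), although both medians turned positive under scaling to the ribosomal protein genes. The largest differences in the latter were ndufs6 (6.98 FPKM in control, 1.24 in WGA embryos) and ndufa5 (9.1 and 2.16 FPKM). The lipid kinase and lipid phosphatase families lay on the other side under each scaling tried. Myotubularin genes, a family that includes phosphoinositide phosphatases, had a median of 1.00 at 4.3 hpf with 6 of 12 higher by 2-fold or more and 0 lower, and 0.68 at 5 hpf. Among them mtmr14 was at 5.49 FPKM in control and 17.3 in WGA embryos. Phosphoinositide kinase genes, with regulatory subunit genes counted in, had a median of 0.64 at 4.3 hpf with 4 of 18 higher and 0 lower. Among the higher ones was the regulatory subunit gene pik3r3b, at 15.41 and 52.07 FPKM. None of the scalings tried corrects for transcript length. The library sums correspond to an FPKM-weighted mean length of 2323 nt in control, 2493 nt in WGA at 4.3 hpf and 2432 nt in WGA at 5 hpf. This holds if every mapped fragment was counted on a listed gene. The check of gene length was not run, so a length-dependent difference between libraries remains open for the higher and the lower families.

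The lower level of zygotic genes is the main pattern of these data. Scaling as its cause is argued against, because the first-wave median at 4.3 hpf was -1.52 or lower under each of the other 3 scalings. A difference in depth is also argued against for the first-wave list, because it would act alike on genes of similar expression. At 4.3 hpf the first-wave median was -2.178 (SD over members 0.55), and 0 of 10000 expression-matched random lists were as low. The median of all genes was 0.029 (standard deviation 0.773). The depth estimate for the WGA library at 4.3 hpf was 3.4% against control. That estimate alone does not decide the question. Only ratios close to equal depth were searched for it, so a difference as large as the change itself could not have been found. Later morphological staging alone would place the first-wave list near control at the matched stage, where its median was -1.99, so a delay of gene activation beyond that of shape, a block by WGA and an effect of injection all remain open and untested. An atypical control library cannot be told apart from these, because there is only 1 control library.

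The second pattern is the set of 1028 genes at least 2-fold higher in WGA embryos at 4.3 hpf, among them buc, tdrd6, sox19b and cpeb1b. A larger share of all remaining transcripts, as would follow if zygotic ones were fewer, would lift the median gene by about as much. The median log2 ratio of all genes was 0.029 as deposited (standard deviation 0.773) and 0.127 in TPM (0.885), which argues against this as the whole cause. The higher genes had medians of 1.298 and 1.308, but these exceed 2-fold by selection and add nothing to the argument. The median of all genes was 0.68 under ribosomal protein scaling, which does not measure a share. A candidate explanation is delayed clearance of maternal transcripts. By it the fixed oocyte and maternal list would lie below the random band between the WGA times. The criterion set had a second part, a value above the band at 5 hpf against control. Only a delay beyond that of shape calls for this second part. Between the WGA times its median was -0.086 (23 of 41 members lower, percentile 0.16 of random lists), -0.032 under median-of-ratios and -0.429 under ribosomal protein scaling. Against control at 5 hpf its median was 0.024 at percentile 86.11, inside the random band, so the second part was not met. A delay no longer than that of shape would also leave the list near control there. The unmet second part therefore does not count against delayed clearance as such. The comparison between the WGA times shares the WGA library at 4.3 hpf with the first one, and the list of maternal regulators lay inside the random band there (percentile 25.16). Since buc and cpeb1b were not lower at 5 hpf and sox19b was level (292.6 and 291.64 FPKM), the explanation is open.

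The third pattern is a subset of numbered zinc-finger genes with lower values in WGA embryos. Of 105 measured, 56 lay below control at 4.3 hpf, 27 of them by 2-fold or more, and 4 were higher, with a family median of -0.04 at percentile 3.52, inside the random band, whose sign changed under TPM and ribosomal protein scaling. At 5 hpf 67 lay below control, 24 by 2-fold or more, and 3 were higher (median -0.26 at percentile 0.0, also negative under the other 3 scalings). Reads moved between copies within the family would raise some members by what others lose. As deposited, all members above control together gained 39.7% of the FPKM lost by those below it at 4.3 hpf and 30.5% at 5 hpf, which argues against this as the whole cause, while reads moved to copies under other names, and a biological cause, were not tested.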
